A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

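The samples were 6 RNA libraries of 1 Saccharomyces cerevisiae strain, 3 collected at 0 min and 3 at 180 min after 1 µM beta-estradiol, from 3 independent experiments per the labels. Per the labels' protocols, RNA was extracted from snap-frozen cells, treated with DNase, and made into stranded polyA-selected libraries with a dUTP method. Groups were taken from the title of each sample, which also gives the replicate number.

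The authors deposited a table of counts, whole-number read counts per gene that are not normalized, with 7127 genes and 1 column per library. Per the submitters' processing notes, bcl2fastq 2.20.0.422, cutadapt 1.10, STAR 2.5.3a and HTSeq 0.6.1p1 were used, with the genome builds R64 and sacCer3. The strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Both identical copies CUP1-1 and CUP1-2 had 0 counts in all 6 libraries. Counts of overlapping genes, antisense pairs and near-identical paralogs are therefore uncertain.

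Gene names, biotypes and positions came from the RefSeq annotation of the same build, R64. Of the 7127 identifiers, 6047 matched by locus tag and 41 by symbol, and the 1039 without a match, which held 0.469% of counts, kept the identifier of the file. No row was a total or an unassigned class.

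Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM composition factors, its default filter on low counts by group, a quasi-likelihood F test of 180 min against 0 min, two-sided, and Benjamini-Hochberg adjustment over the 6220 genes that passed the filter. The filter removed 907 genes. A gene was called at an adjusted p below 0.05. Standard errors and 95% confidence intervals of the log2 fold change came from the same fit. A gene was bounded within 2-fold when the interval lay between -1 and 1. CPM are counts scaled to the TMM-adjusted library size, computed here. Mean TMM factors were 0.916 ± 0.0135 at 0 min and 1.09 ± 0.0165 at 180 min (SD, n = 3).

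Before the data were examined, 44 gene lists were fixed from textbook knowledge, together with the tests, the alternatives and the rule for named genes. The 43 lists with at least 3 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over the 43 lists. The list of genes specific to MATalpha cells was below the minimum. The result of 1 tested list is not reported here. With an estimated correlation camera called 0 lists (3 at an unadjusted p below 0.05), and fry, which tests each list on its own, called 25. The lists called with the preset correlation were all among these 25, in the same direction. Strain marker genes were left out of the lists, and 1 list member, CRS5, had no match.

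Named genes are the strain loci and the annotated neighbours of SHS1 within 5 kb, the condensin genes, the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 counts whose groups did not overlap, and, per list, up to 4 called members with the smallest adjusted p. Other members are named where they are exceptions of a list, hexose transporters or septin genes, and these were chosen after their values were seen.

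Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, protein-coding nuclear genes alone, a test against a 1.5-fold change, a stricter threshold, and other list tests. Scaling factors computed without ribosomal genes, and removal of a loess trend on gene length and GC content, were added after seeing the data. Gene length is the span of the annotated gene from start to stop codon, with no UTRs.

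The gene and list tests were tested on simulated counts with the means, dispersions and library sizes of this comparison over 6220 genes, of which 200 were changed. The edgeR test recovered 30% of 50 genes changed 1.2-fold, 76% of 50 changed 1.5-fold, 84% of 50 changed 2-fold and 94% of 50 changed 4-fold, with 2 false calls among 144. All 45 genes changed 4-fold with a mean of at least 50 counts were recovered, so the misses at that size were genes with few counts. DESeq2 made 15 false calls among 164. In the same simulation camera gave a list of 25 genes raised 2-fold a p of 5.01e-50 and a list of 25 genes not changed a p of 0.551. For these lists fry gave 4.1e-06 and 0.556. Simulated genes varied independently, so this could not test the preset correlation of 0.01. In the data the lists called by camera had estimated correlations between 0.0566 and 0.746. At 25,987,900 to 34,032,212 counts per library, the edgeR test often missed 1.2-fold changes in the simulation. The shares it recovered there need not carry over to the data. In the data 3587 genes were called, against 144 in the simulation, which makes the adjusted threshold less strict. Drawing used matplotlib 3.10.9.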

Results

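Polyadenylated RNA was sequenced from a haploid MATa budding yeast strain of the S288c background grown in rich medium (YPD). In this strain the 3' end of SHS1, a septin gene, carries a loxP-flanked mCherry sequence followed by GFP. A Cre recombinase fused to an estrogen-binding domain, inserted at leu2, removes the mCherry sequence once beta-estradiol is added. Cells were collected at 0 min (mCh*, 3 libraries) and 180 min after addition of 1 µM beta-estradiol (mCh-, 3 libraries), from 3 independent experiments per the labels. Total gene counts per library lay between 25,987,900 and 34,032,212, with a mean of 30,327,900 ± 2,550,400 (SD, n = 3) at 0 min and 30,467,700 ± 4,099,500 (SD, n = 3) at 180 min. Spearman correlations were 0.994 to 0.996 between libraries of the same time and 0.958 to 0.968 between times, across genes, which are not independent replicates. The chi-square statistic per degree of freedom was at least 25.7 in every pair of libraries of the same time, so no pair agreed within counting noise.

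The comparison of 180 min with 0 min asked how the transcriptome differed between the cells before the hormone and the cells after the reporter switch. At 180 min, transcripts of ribosomal proteins and ribosome assembly factors were lower, and transcripts of the environmental stress response, chaperones and storage carbohydrate metabolism were higher. Ribosomal protein genes took 33.1 ± 0.398% of all counts at 0 min and 21.0 ± 0.150% at 180 min (SD, n = 3), while genes induced in the environmental stress response took 1.13 ± 0.0403% and 2.98 ± 0.148%. The secreted glycoprotein gene YGP1 and the glycogen phosphorylase gene GPH1 were among the strongest rises, and the phosphate transporter gene PHO84 had the strongest fall among the genes selected by size. SHS1 itself was not called, at 68.0 ± 0.674 CPM (counts scaled to library size) at 0 min and 72.2 ± 2.37 CPM at 180 min (SD, n = 3).

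Of 6220 genes tested, 3587 (57.7%) were called at an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1833 higher and 1754 lower at 180 min. Calls at least 2-fold in size numbered 286 higher and 280 lower. The 95% confidence interval of the log2 fold change lay wholly within a 2-fold change in either direction for 4651 genes (74.8%). In 3946 genes (63.4%, against 10% by chance) all 3 libraries of one time lay above all 3 of the other. With library sizes only, without composition factors, the calls were 2996 higher and 969 lower (75.6% higher in place of 51.1%), and the median log2 fold change of all genes moved to 0.27 from 0.02. The p-values weigh the difference between the times against the spread among the 3 libraries of each time. The groups differ at once in time in culture, hormone and reporter allele, and no library separates these.

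**Figure D1:**
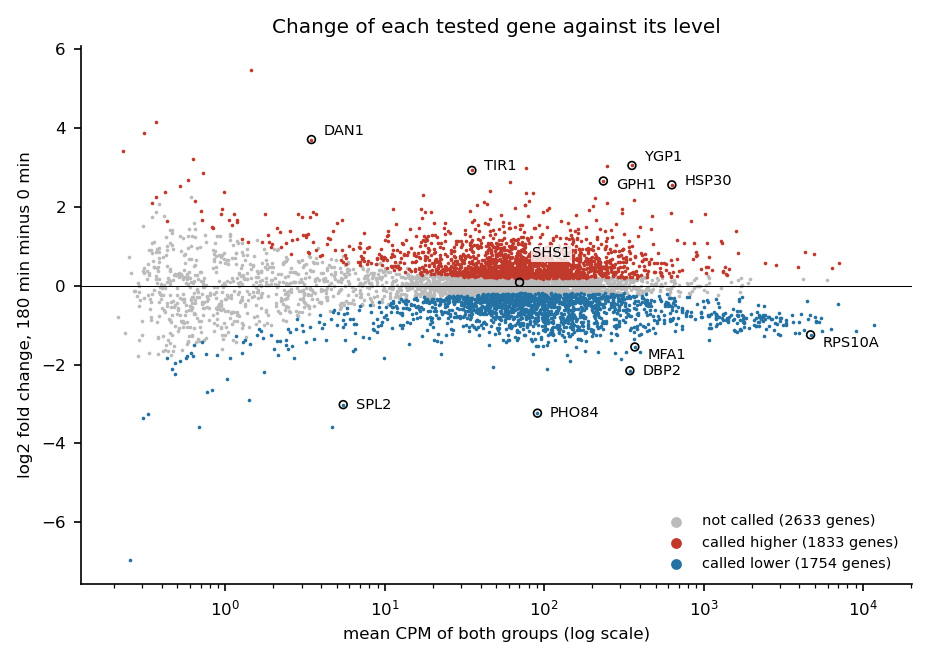
Log2 fold change (180 min minus 0 min, vertical axis) of each of the 6220 tested genes against its mean CPM over both groups (horizontal log axis). Each point is a gene, red for the 1833 called higher, blue for the 1754 called lower and grey for genes not called, and the most abundant genes lie mostly below 0, RPS10A among them.

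At the engineered locus, SHS1 (YDL225W, chromosome IV, 52445 to 54100 in R64) had a log2 fold change of 0.09 ± 0.08 (SE), with an adjusted p of 0.344 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With library sizes only it was 0.34 (adjusted p = 0.00138 in edgeR), most of which is the shift of all genes. Because mCherry and GFP are not yeast sequences, the SHS1 count does not measure the excision. Among the annotated genes within 5 kb, HBT1 (0.04, called at 0.29 with library sizes only) and WHI4 (-0.09) were not called, HO, the mating-type switching endonuclease, fell by 0.78, and GCS1 fell by 0.19. The GCS1 call (adjusted p = 0.0485 in edgeR) was lost without any 1 of 4 single libraries, with adjusted p of 0.0755 to 0.162, and also without a filter (0.0580) and with a trend on gene length and GC content removed (0.0746). Its value was 0.06 with library sizes only. CLN2, the G1 cyclin whose 3' UTR is part of the cassette, fell by 0.42 ± 0.09 on the log2 scale, from 66.3 to 49.6 CPM, and was not called with library sizes only (-0.16). Of the other loci used to build the strain, TRP1 (0.82) and LEU2 (0.40) were higher, and HIS3 (-0.53) and ADE2 (-0.73) lower. LYS4 (0.27, adjusted p = 0.0428 in edgeR) was no longer called without mCh*_t0 replicate 1 (adjusted p = 0.115), mCh*_t0 replicate 2 (0.150) or mCh-_t180 replicate 3 (0.316). It was also not called with DESeq2's size factors (0.0569), with factors computed without ribosomal genes (0.0798) or with the length and GC trend removed (0.0896). These genes can also share reads with the inserted markers, which makes their counts uncertain.

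Protein synthesis genes fell. Of 138 ribosomal protein genes, 136 fell and 2 were not called, with a median log2 fold change of -0.84, and adjusted over the list alone the count was also 136. RPS10A (-1.25 ± 0.10 SE) went from 6606 to 2784 CPM and RPL1A (-1.14 ± 0.09 SE) from 912 to 413 CPM. The members not called, RPL15B (0.00) and RPL9B (-0.13), were singled out after their values were seen. Many ribosomal protein genes have near-identical copies, so how counts are split between the copies is uncertain. With the length and GC trend removed, a setting chosen after seeing the data, the median of the ribosomal protein genes was -0.78. Of 133 ribosome biogenesis genes, 132 fell, with a median of -0.96, and SRO9 (0.20, singled out after its value was seen) was not called, except with library sizes only (0.46). DBP2, an RNA helicase, fell by 2.16, from 564 to 126 CPM, ENP2 fell by 1.54 and RPF2, a factor of large subunit assembly, by 1.36. Adjusted over the list alone the count of the biogenesis list was also 132. Camera, which compares a list with all other genes, called the ribosomal protein list (adjusted p = 7.90e-31) and the biogenesis list (adjusted p = 6.24e-35) lower with a preset correlation of 0.01. Neither call held in camera with an estimated correlation (adjusted p = 0.402 for both lists), a setting that called 0 lists. Fry, which tests each list on its own, called both lower (adjusted p = 0.000312 and 0.000151).

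Stress and storage genes rose. Of 91 tested genes induced in the environmental stress response, 85 rose, 0 fell and 6 were not called, with a median log2 fold change of 1.09 and the same counts adjusted over the list alone. TFS1, an inhibitor of carboxypeptidase Y, rose by 2.36 ± 0.08 (SE), RTN2 by 2.04 and GAD1, glutamate decarboxylase, by 1.93. Camera gave this list an adjusted p = 1.10e-22 with the preset correlation and an adjusted p = 0.216 with an estimated correlation. All 17 genes of trehalose and glycogen metabolism rose, with a median of 1.07, and adjusted over the list alone the count was again 17. Glycogen synthase GSY2 rose by 2.03 ± 0.11 (SE), phosphoglucomutase PGM2 by 2.11 and the debranching enzyme GDB1 by 1.78. Its camera values were an adjusted p = 2.71e-07 with the preset correlation and an adjusted p = 0.597 with an estimated correlation. Of 25 chaperone genes controlled by the heat shock factor Hsf1, 19 rose and 2 fell, with a median of 0.60 and the same counts adjusted over the list alone. HSP78 (2.22), HSP82 (1.78) and HSP42 (1.45) rose, whereas SSE1 (-0.43) and YDJ1 (-0.31), named after their values were seen, fell. Camera gave the chaperone list an adjusted p = 2.53e-05 with the preset correlation and an adjusted p = 0.586 with an estimated correlation. The stress list shares 9 genes with the storage list and 5 with the chaperone list. Under library sizes only, SSE1 and YDJ1 were not called.

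**Figure D2:**
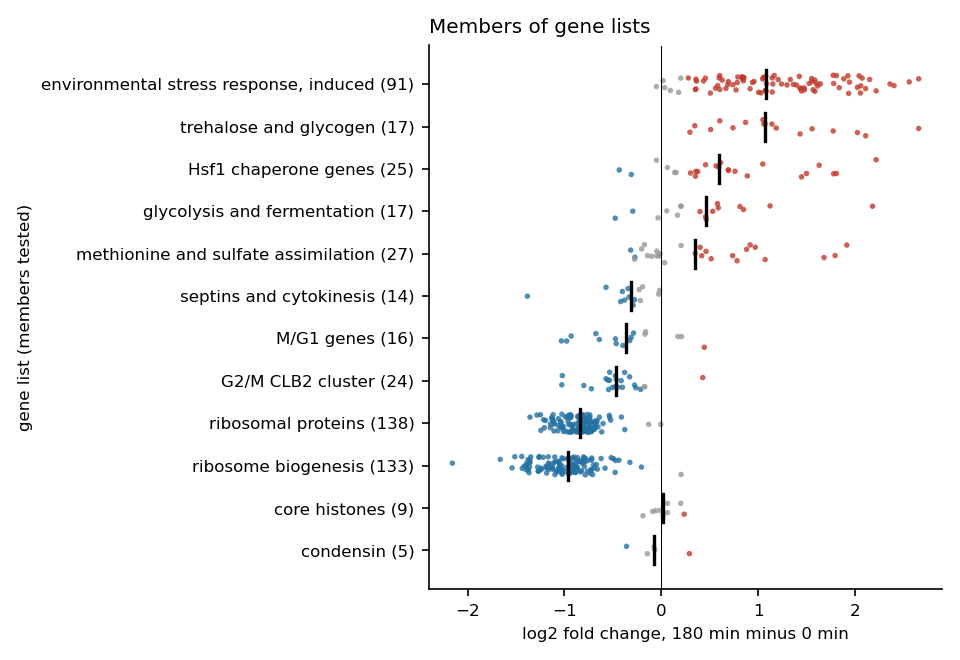
Log2 fold change (180 min minus 0 min, horizontal axis) of each member of the 10 gene lists called by camera and of the core histone and condensin lists (rows, with the number of members tested). Points are genes, red if called higher, blue if called lower and grey if not called, and the black bar is the median, which runs from 1.09 for the stress list to -0.96 for ribosome biogenesis.

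Glycolytic genes moved mainly upward. Of 17 genes of glycolysis and fermentation, 10 rose and 2 fell, with 11 and 2 adjusted over the list alone and a median of 0.46. TDH1, a glyceraldehyde-3-phosphate dehydrogenase, rose by 2.18 ± 0.10 (SE) from 132 to 597 CPM, ENO1 by 1.12 and PGK1 by 0.85. PDC1 (-0.47) and HXK2 (-0.29), named after their values were seen, fell. The HXK2 call was lost without mCh*_t0 replicate 2 (adjusted p = 0.0775 in edgeR), and neither gene was called with library sizes only. Camera called the list higher (adjusted p = 0.0106), with an adjusted p = 0.712 with an estimated correlation. In hexose transport, 4 of 18 genes rose and 5 fell, with 3 and 4 adjusted over the list alone. HXT1 (-1.68) and HXT3 (-1.14), low-affinity transporters, and HXT2 (-1.11) fell, while HXT5 (0.91), HXT6 (2.30) and HXT7 (0.56) rose. HXT6 and HXT7 are near-identical, so the division of their counts is uncertain. HXT4 (0.16) was not called, except with library sizes only (0.41). The median (0.10) and mean (0.07) of this list lay above 0 while camera gave it a downward direction, with an adjusted p of 0.876. Of 27 genes of methionine synthesis and sulfate assimilation, 14 rose and 2 fell, with a median of 0.35 and the same counts adjusted over the list alone. MET17 rose by 1.92 ± 0.09 (SE), MET6 by 1.80 and SAM2 by 1.68, whereas CYS4 (-0.27) and MMP1 (-0.32), named after their values were seen, fell. Neither was called with library sizes only, and CYS4 was not called without mCh*_t0 replicate 2 (adjusted p = 0.103 in edgeR), mCh-_t180 replicate 1 (0.0800) or mCh-_t180 replicate 2 (0.0724). Camera called this list higher (adjusted p = 0.0475), with an adjusted p = 0.661 with an estimated correlation, and the call was lost without mCh*_t0 replicate 3 (adjusted p = 0.0826) and with nuclear protein-coding genes alone (0.0529).

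Genes transcribed late in the cell cycle were lower. In the CLB2 cluster, expressed at G2/M, 21 of 24 genes fell and 1 rose, with a median of -0.47 and the same counts adjusted over the list alone. The mitotic cyclin CLB2 fell by 1.03 ± 0.09 (SE), from 61.8 to 30.3 CPM, the kinase gene KIN3 by 1.02 and CDC20, an activator of the anaphase-promoting complex, by 0.80. NUM1 (0.43), singled out after its value was seen, rose, and was not called with the length and GC trend removed (0.08). Camera gave an adjusted p = 2.17e-05 with the preset correlation and an adjusted p = 0.586 with an estimated correlation. Of 16 genes expressed at the M/G1 boundary, 11 fell and 1 rose, with 11 and 2 adjusted over the list alone, and the median was -0.36. FAR1, a cyclin-dependent kinase inhibitor, fell by 0.93, PIR1, a cell wall protein gene, by 0.98 and PCL9, a cyclin gene, by 0.67, while YPS1 (0.45) rose. This list had an adjusted p = 0.0281 in camera with the preset correlation and an adjusted p = 0.586 with an estimated correlation. In septins and cytokinesis, 9 of 14 genes fell and 0 rose, with 11 falling adjusted over the list alone and a median of -0.31. The largest fall there was GIC2 (-1.38), a Cdc42 effector, with HOF1 at -0.57, while of the septins themselves CDC12 (-0.33) fell and CDC11 (-0.19), CDC3 (-0.02) and CDC10 (-0.03) were not called. With library sizes only, CDC3 (0.24) and CDC10 (0.23) were called higher and CDC12 was not called. CDC11, with an adjusted p of 0.0509 in edgeR, was called lower without mCh*_t0 replicate 3 (0.0254) or mCh-_t180 replicate 3 (0.0291), and under some of the other scalings, filters, gene sets and tests (0.0248 to 0.0498). Camera gave an adjusted p = 0.0109 for this list, an adjusted p = 0.597 with an estimated correlation, and 0.0565 with library sizes only. The list shares 4 genes with the CLB2 cluster.

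Camera did not call the condensin, histone or cohesin lists. Among the 5 condensin genes, SMC2 was higher (0.29 ± 0.08 SE, adjusted p = 0.00440 in edgeR's quasi-likelihood test) and BRN1 lower (-0.36 ± 0.10 SE, adjusted p = 0.00732), with 1 higher and 1 lower also adjusted over the list alone. SMC4 (-0.07), YCS4 (-0.06) and YCG1 (-0.14) were not called, and camera gave the list an adjusted p of 0.782. Beside these values, protein-coding genes spanning over 3000 bases had a median log2 fold change of 0.27 (265 of 492 called higher and 65 lower), and SMC2, SMC4, YCS4 and YCG1 span 3108 to 4257 bases. With the length and GC trend removed, SMC2 was at 0.06 and not called, and SMC4 (-0.35), YCS4 (-0.31) and YCG1 (-0.35) were called lower. BRN1 was not called with library sizes only (-0.10). Of 9 histone genes only HHO1, the linker histone, was called (0.24), and adjusted over the list alone the count was 0. The HHO1 call was lost without mCh*_t0 replicate 2 (adjusted p = 0.0527 in edgeR), mCh*_t0 replicate 3 (0.0648) or mCh-_t180 replicate 3 (0.0643). For the histone list the camera adjusted p was 0.876. Of 18 genes of cohesin, Smc5/6 and topoisomerases, 3 rose and 5 fell, with the same counts adjusted over the list alone, and the median (0.06) and mean (-0.01) differed in sign (camera adjusted p = 0.958).

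The 10 largest rises among called genes with a mean of at least 50 counts were DAN1 (3.71), YGP1 (3.05), EGO4 (3.03), YNL194C (2.99), TIR1 (2.93), GPH1 (2.66), DCS2 (2.64), HSP30 (2.56), AMS1 (2.41) and TFS1 (2.36). DAN1 and TIR1 encode cell wall mannoproteins of anaerobic growth, HSP30 a plasma membrane heat shock protein, and AMS1 vacuolar alpha-mannosidase. DAN1 was scarce, at 0.484 ± 0.162 and 6.44 ± 1.55 CPM, while YGP1 went from 76.4 ± 6.98 to 634 ± 140 CPM and GPH1 from 64.3 ± 7.57 to 406 ± 99.4 CPM (SD, n = 3). HSP30 went from 183 ± 76.3 to 1082 ± 75.9 CPM. The 10 largest falls were PHO84 (-3.24), SPL2 (-3.02), the tRNA gene tE(UUC)K (-2.18), DBP2 (-2.16), ATO3 (-2.11), RCK1 (-2.05), AAH1 (-1.90), CGR1 (-1.86), the tRNA gene tK(CUU)M (-1.85) and YDR042C (-1.84). AAH1 encodes adenine deaminase and CGR1 a factor of ribosome assembly. PHO84, the high-affinity phosphate transporter, went from 164 ± 18.9 to 17.3 ± 13.3 CPM, and without mCh-_t180 replicate 3, which had 32.6 CPM, its log2 fold change was -4.11. The tRNA genes had means under 5 CPM at both times, and tRNA is not selected for by its tail, so these values are uncertain.

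**Figure D3:**
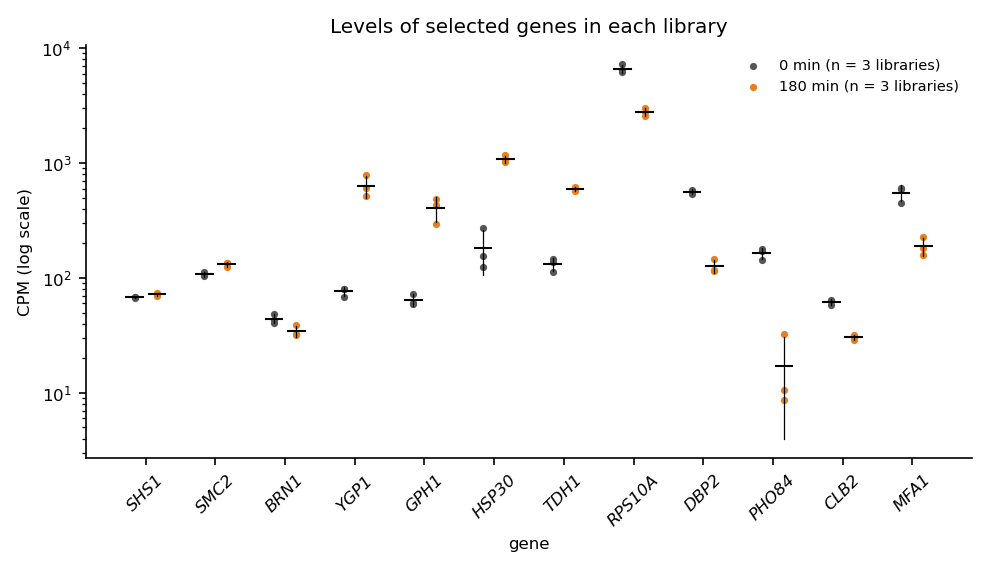
CPM (vertical log axis) of 12 genes in each library at 0 min (grey) and 180 min (orange), with 3 libraries per time. Points are libraries, horizontal bars are means and vertical bars SD, and SHS1 lies near 70 CPM at both times while PHO84 lies at 17.3 CPM or 164 CPM on average.

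Camera did not call the other 33 lists, several of which held called genes moving both ways. In the phosphate regulon 9 of 17 genes fell and 3 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.150). VTC1 (-0.78), of the polyphosphate synthase complex, fell with PHO84 and SPL2, while GPP2 (1.24), a glycerol-3-phosphate phosphatase, rose. In purine biosynthesis 12 of 17 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.0550), with HPT1 (-1.38) and ADE4 (-0.96) among the falls. This list was called lower without mCh*_t0 replicate 3 (adjusted p = 0.0236), mCh-_t180 replicate 2 (0.0491) or mCh-_t180 replicate 3 (0.0468). Of 19 hypoxic and anaerobic genes 10 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0636), and the list was called without mCh-_t180 replicate 1 (0.0438) or mCh-_t180 replicate 2 (0.0491). In the unfolded protein response 9 of 17 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0541), with the chaperone KAR2 at 1.08. It was called without mCh*_t0 replicate 1 (0.0344), mCh-_t180 replicate 1 (0.0438) or mCh-_t180 replicate 2 (0.0319). In the TCA cycle 9 of 15 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0636), with KGD1 at 0.72, and the list was called without mCh-_t180 replicate 1 (0.0438). Of 56 mitochondrial ribosomal protein genes 19 rose and 3 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.0638), and the list was called without mCh*_t0 replicate 1 (0.0253) or mCh-_t180 replicate 1 (0.0438).

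Genes specific to the MATa mating type fell in 4 of 7 cases, also adjusted over the list alone (camera adjusted p = 0.215). They were the a-factor genes MFA1 (-1.55) and MFA2 (-0.95), its exporter STE6 (-0.45) and the receptor STE2 (-0.30). The STE2 call was lost without mCh*_t0 replicate 2 (adjusted p = 0.0520 in edgeR) or mCh-_t180 replicate 2 (0.0594), and neither STE6 nor STE2 was called with library sizes only. Among genes of the other mating type, STE3 stood at 5.05 and 5.67 CPM and was not called. In the pheromone response 3 of 22 rose and 11 fell, with PRM8 at 1.15 and PRM5 at -0.92. Of 28 genes of meiosis and sporulation 5 rose and 3 fell (3 and 2 adjusted over the list alone). In the G1/S list 3 of 40 rose and 16 fell (3 and 15 adjusted over the list alone, camera adjusted p = 0.214). With the length and GC trend removed camera called it lower (median -0.21, adjusted p = 0.0399). Amino acid biosynthesis had 15 higher and 20 lower of 52, with ARG4 at 1.42 and ILV5 at -1.25. Drug resistance genes had 8 higher and 3 lower of 19, with the transporter PDR15 at 1.37. The iron regulon had 4 higher and 9 lower of 28, with the ferroxidase FET3 at -1.01. The DNA damage response had 7 higher and 2 lower of 16, with TSA2, a peroxiredoxin, at 2.34.

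The remaining lists gave smaller or mixed counts. Ergosterol biosynthesis had 11 higher and 3 lower of 26, the oxidative stress list 10 and 2 of 24, cell wall integrity 5 and 11 of 22, and nitrogen catabolite repression 5 and 6 of 25. The respiratory chain had 8 higher and 7 lower of 35, the proteasome 4 and 7 of 34, gluconeogenesis 4 and 4 of 22, and peroxisomal fatty acid oxidation 4 and 2 of 14. Vitamin B6 and thiamine genes had 1 higher and 3 lower of 21, zinc 1 and 3 of 11, copper 2 and 3 of 6, galactose 2 and 0 of 8 and seripauperins 1 and 0 of 9. No call was made among the 5 tested genes encoded in mitochondria, which took under 0.001% of counts. Adjusted over the list alone, the counts were 8 and 6 for the respiratory chain, 1 and 0 for the proteasome, 3 and 3 for gluconeogenesis, 3 and 6 for nitrogen catabolite repression and 0 and 3 for vitamin B6 and thiamine. For the pheromone, amino acid, drug resistance, iron, DNA damage, ergosterol, oxidative stress, cell wall, peroxisomal, zinc, copper, galactose and seripauperin lists, the counts adjusted over the list alone were the same.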

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

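The scaling without ribosomal genes and the removal of a trend on gene length and GC content were chosen after seeing the data. The count of called genes stayed within 1.5 times of 3587 under all settings except the test against a 1.5-fold change, which called 905, and lay between 3143 and 3477 with 1 library left out. Over the settings that change the scaling, filter, tool, block, gene set or libraries at the same threshold, 78.1% to 99.02% of calls were kept and none was called in the opposite direction. With library sizes only, 2996 genes were called higher and 969 lower, because that setting shifts the median log2 fold change to 0.27. GCS1 (0.062), CDC3 (0.24) and CDC10 (0.23) changed sign there and SHS1 (0.34) was called, each having moved up with that shift. With 1 library left out, calls lay between 1597 and 1767 higher and between 1546 and 1710 lower, SHS1 between 0.06 and 0.10, and genes bounded within 2-fold between 4492 and 4581. A 1.5-fold bound held 2956 genes in place of 4651. Lists called numbered 10, 0 with an estimated correlation (3 at an unadjusted p below 0.05), 25 by fry, 16 with the length and GC trend removed, and 10 to 14 with 1 library left out. For 102 named genes other than SHS1, 1578 of their values under other settings gave the same result, 35 lost the call and 14 gained it. The same result here means called in the same direction, or not called in either setting. For 43 lists, 10 of them called, 615 values gave the same result, 4 lost the call and 24 gained it, and none changed direction with a call. The estimated correlation, with which 0 lists were called, and fry are not part of these list counts. The gains with all 6 libraries were the mitochondrial ribosomal protein, TCA cycle, purine and unfolded protein response lists without a filter, the same lists without the TCA cycle with library sizes only, and those 4 with the G1/S and hypoxic lists once the length and GC trend was removed. With the replicate number as a block, 3390 genes (3370 of the calls kept) and 9 lists were called, and methionine and sulfate assimilation (adjusted p = 0.0621) was the list lost. GCS1 (adjusted p = 0.0843) was the named gene whose call the block changed. The numbers were not treated as pairs, since libraries with the same number did not deviate together (correlations -0.0197, -0.0328 and -0.179) and no library correlated best with its own number. The cause of the other changes was not tested.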

Other observations

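The tests of composition factors, of length and GC content on ribosomal genes, of glucose, of histone genes and of list members among long genes were chosen after the result was seen. The other tests were set before their result was seen.

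Longer genes were higher at 180 min. The median log2 fold change rose from -0.07 in 732 protein-coding genes of up to 500 bases to 0.27 in 492 genes over 3000 bases. The slope of log2 CPM on log2 length was taken over protein-coding genes outside the fixed lists. It was higher by 0.0757 at 180 min than at 0 min, with an SD between libraries of 0.0165 at 0 min and 0.00870 at 180 min (n = 3 each). Without the members of the fixed lists the median of 412 long genes was still 0.29 (0.2915), which argues against those lists as the cause. Shorter genes matched on mean log2 CPM had medians between -0.08 and 0.05 in the central 99% of 10000 random lists. The long genes had 0.2678, so the level in CPM does not account for their shift. CPM is not corrected for gene length, so the level of transcripts was not matched and its part was not tested. A difference in RNA quality or library preparation between the groups may remain, and since each library is in 1 group, it cannot be told apart from a biological difference.

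The fall of ribosomal protein genes kept its direction under 3 other scalings, where their median was -0.5817 at most, with library sizes only, and -0.7778 was left in 138 genes after the length and GC trend was removed. Another scaling moves all genes by about the same amount, with library sizes only to a median log2 fold change of 0.27. The scalings thus show only that the fall is larger than such a shift, which argues against the composition factors as the whole cause. The value left after the correction argues against the length and GC trend as the whole cause. A change in total mRNA per cell, which no scaling of these counts can show, was not tested. Glucose exhaustion by 180 min would raise the genes of gluconeogenesis and acetate use. The 22 genes had a median of 0.0930 and an upper quartile of 0.41, with 4 called higher, CAT8 (0.99) among them, and 4 lower. This argues against exhaustion, though not against a smaller decline in glucose. In hexose transport 4 of 18 genes rose and 5 fell, with HXT6 at 2.30 and HXT1 at -1.68. All 17 genes of trehalose and glycogen metabolism rose. Whether these changes follow a decline in glucose was not tested. Time in culture, the hormone and the reporter switch stay open, since the groups differ in all of them.

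The fall of the CLB2 cluster (median -0.47) could follow from fewer dividing cells in every phase, which would lower the S-phase histone genes alike. The 9 histone genes had a median of 0.0191 and quartiles of -0.06 and 0.07, all above the cluster's median, which argues against an equal loss of dividing cells in every phase. The G1/S list goes partly with a loss, with 16 of 40 genes lower and 3 higher, and camera called it lower only with the length and GC trend removed among the settings run (median -0.21, adjusted p = 0.0399, against 0.214). A shift in the share of cells per phase was not tested.

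Because the series concerns chromatin, protein-coding genes within 20 kb of a chromosome end that passed the low-count filter were tested as a group. Their median was 0.0741 over 149 genes (37 called higher and 19 lower), inside the central 99% of 10000 lists matched on expression (-0.04 to 0.21). No common shift was thus seen among them. Genes near chromosome ends that the filter removed were not covered.

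Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real one, namely itself (3587). The highest other split called 0 genes in edgeR, with up to 116 at an unadjusted p below 0.05, 0 in limma-voom and 1 in DESeq2. Each other split mixed libraries of both times in each part, so the difference between times added to its spread and lowered its count. These counts thus do not show how many genes a comparison without a difference would call. The splits are also too few for a share under 0.05.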
